A study of Mus musculus with 2 samples.

How the data were processed

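RNA from the hindbrain of 2 mouse pups of strain B6NCrl was sequenced at postnatal day 0. Per the labels, RNA was extracted with the mirVana method, the size range was above 200 nt, and each library started from 13 pg, called 1 cell-equivalent. The labels name the molecule as total RNA and the assay as single cell RNA-seq, and point to a Smart-seq protocol, a method that usually primes from poly(A) tails. The 2 libraries form 1 group, P0 hindbrain, with pup 1 as replicate 1 and pup 3 as replicate 2, each with technical replicate 1. The labels give both pups the same donor record, and their sex as not collected.

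The authors deposited 1 gene table and 1 transcript table per library, made on the mm10 assembly with annotation M4 from alignments to the transcriptome, per the deposited notes that accompany the tables. Per the file headers, each table gives an expected count, an estimate in which a read shared among transcripts is split, so values need not be whole. The deposited TPM values (transcripts scaled to a fixed total) are relative to everything listed, spike-ins and mitochondrial genes included. The deposited FPKM values are scaled to effective length and to the assigned reads. The transcript tables give, per the file headers, the percent of a gene's TPM that each transcript takes. The columns have the layout of the quantifier RSEM. The aligner, the versions and whether strand was used in counting are not given in the sources used here. Multiply mapping reads are split by such estimates, so near-identical genes are uncertain individually, and without strand the reads of overlapping or antisense genes cannot be told apart.

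The tables listed 69691 entries: 43346 mouse genes, 96 ERCC spike-ins, 1 phiX entry and 26248 entries with a number for a name, which were left out of all comparisons. Of the mouse gene identifiers 42462 (98.0%) matched by stable identifier to GENCODE M21 on GRCm38, the same assembly, from which symbols, biotypes and coordinates were taken. Coordinates are 1-based. TPM was rescaled to the same fixed total over the 43309 nuclear genes, so that genes annotated as mitochondrial and spike-ins did not enter the total. Nuclear copies of mitochondrial sequence stayed in it. The correlations, the shares of missing genes by level and the differences by level used the deposited TPM. The total expected count was 35462381 in pup 1 and 29866728 in pup 3. A gene was called detected at an expected count of at least 5. A pseudocount of 1 was added before log2, which understates the differences of low genes. A difference of 4-fold was counted among genes with an expected count of at least 50 in at least 1 library. Where a library had 0 counts, the fold is a lower bound computed against 3 counts in that library. With 1 to 3 counts, the ratio of the shares of nuclear counts is given with a 95% counting interval for Mtx1 and Ubl7. For other such genes only counts or TPM are given. The intervals of shares are Wilson intervals at 95%.

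No test between groups was possible with 1 group. Counting error alone was simulated with 100 draws of a pair of libraries. For each of 39 gene lists, the number of members detected in both libraries was set beside 10000 random lists of protein-coding genes of the same size. The median log2 ratio of pup 3 over pup 1 was set beside 10000 random lists of the same size matched on mean expression in 20 bins, for the 37 lists with at least 5 detected members. These percentiles describe the 2 libraries, and since members of a list can vary together they are no test of the pups. Of the listed symbols 4 had no match. Lists share some members, such as Ttr, Igf2, Zic1, Mycn and Actb.

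The gene lists, thresholds, alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 4 members of each list with the highest mean TPM, any member of a list of another region or tissue detected in both libraries, the 10 most abundant protein-coding genes outside the ribosomal proteins, the 10 protein-coding genes with the largest difference in each direction, the 10 most abundant non-coding nuclear RNAs, and the 15 isoform genes. Further list members named in the text, together with Gm26917, Arpc3 and Pabpn1, were chosen after their values were seen. Some genes that the rule names are not reported here.

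Alternatives tried were detection at an expected count of at least 1 or 10 or at 1 TPM, thinning of the deeper library, pseudocounts of 0.1 and 5, folds of 2 and 8, other minimum counts, deposited TPM in place of rescaled TPM, FPKM and CPM in place of TPM, scaling factors from edgeR and DESeq2 on the rounded expected counts, and each library alone. Scaling over protein-coding genes, scaling to the spike-in total and the restriction to genes detected in both libraries were chosen after seeing the data. Across scalings, the median log2 ratio of genes detected in both libraries moved by -0.09 to 0.07 from its main value of 0.12. The fold count was tested on simulated data over 43309 genes, where 100% of 200 genes changed 8-fold and 0% of 200 genes changed 2-fold were called, with 0 unchanged genes called. This simulation drew counting error only and changed well-counted genes only. It checks the calculation and says nothing about calls that arise from transcripts lost at capture. The list comparison was tested on 40 simulated lists drawn from 4000 genes, of which 2.5% fell outside the central 95% with no shift and 100% with a log2 shift of 2. Simulated genes varied independently and with the same spread at every level, unlike the data. This also checks the calculation only, and not which shifts the real lists could show. The ependyma and cilia list, at -2.49, lay inside its matched range (-3.29 to 2.18). Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used, with R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 for the scaling factors only.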

Results

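The transcriptome of the newborn mouse hindbrain was sequenced from 2 animals of the B6NCrl strain, labelled pup 1 (replicate 1) and pup 3 (replicate 2), both at postnatal day 0. Each library was made from 13 pg of RNA longer than 200 nt, which the labels call 1 cell-equivalent, from the hindbrain of 1 pup, so each library samples RNA of the tissue's mixed cells at a very small input. The labels give 1 group and no treatment, and the comparison the design allows is between the pups. The pup 1 library held 35462381 expected counts and the pup 3 library 29866728. Spike-in RNAs of the External RNA Controls Consortium (ERCC) took 2.31% of the counts in pup 1 (95% Wilson interval 2.30 to 2.31%) and 2.18% in pup 3 (2.17 to 2.18%). Genes annotated as mitochondrial took 3.33% and 3.11%, without the nuclear copies of mitochondrial sequence, whose reads cannot be told apart from theirs. Levels are in TPM, a length-scaled share of all transcripts, rescaled over nuclear mouse genes, as mean ± SD with n = 2, or for each pup. The correlations, the shares of missing genes by level and the differences by level use the deposited TPM instead. Nuclear genes took 88.6% of the deposited TPM in pup 1 and 89.6% in pup 3. A gene with an expected count of at least 5 is called detected. With 1 library per animal no difference between the pups has a replicate check. Counting intervals and the floor of 3 counts cover counting error only, since amplified reads are not independent molecules. For a transcript with an effective length of 1000 nt, 3 counts correspond to 0.145 TPM in pup 1 and 0.164 TPM in pup 3.

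The most abundant protein-coding gene outside the ribosomal proteins was Tuba1a, the alpha tubulin of young neurons (ENSMUSG00000072235.5, chromosome 15, 98949837 to 98953703), at 17511 ± 352 TPM. Ubb, a polyubiquitin gene, followed at 5863 ± 1036 TPM, with the actins Actb at 5258 ± 1469 TPM and Actg1 at 3891 ± 519 TPM. Stmn1, a microtubule destabiliser of growing neurons, reached 4466 ± 682 TPM, and the ferritin light chain Ftl1 4362 ± 305 TPM. The elongation factor Eef1a1 (4331 ± 2037 TPM), thymosin Tmsb4x (3989 ± 1291 TPM), cyclophilin Ppia (3711 ± 667 TPM) and the beta tubulin Tubb2a (3597 ± 1599 TPM) completed the 10 highest. Tubulin and actin genes have near-identical copies, so reads can be shared among Tuba1a, Tuba1b, Tubb2a and Tubb2b. All 21 genes of axonal transport and the cytoskeleton were detected in both pups, with medians of 898 TPM in pup 1 and 879.8 TPM in pup 3, and so were all 20 housekeeping genes, with medians of 1131 TPM in pup 1 and 997 TPM in pup 3.

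Many transcripts with high counts in 1 pup had none in the other. Of 13847 nuclear genes detected in at least 1 library, 8931 (64.5%) were detected in both, 3320 in pup 1 only and 1596 in pup 3 only. Agt, the angiotensinogen gene of astrocytes, had 6003 counts in pup 1 and 0 in pup 3, and Flt1, a vascular endothelial growth factor receptor, had 0 and 4782. Genes seen in pup 1 only had a median of 338.5 counts there, and genes seen in pup 3 only a median of 361 counts. Under counting error alone, 100 simulated pairs of libraries gave a mean of 356 genes in 1 library only (range 315 to 394), against 4916 observed. The missing share was lower at higher levels. Of protein-coding genes at 10 to 30 deposited TPM in pup 1, 29.8% (95% Wilson interval 28.2 to 31.4%) were not detected in pup 3, against 11.8% (10.7 to 13.0%) at 30 to 100 TPM, 1.42% (0.876 to 2.29%) at 100 to 300 TPM and 0 of 344 genes at 300 to 1000 TPM. In the other direction, of genes at these levels in pup 3, 17.1%, 8.32%, 0.569% and 0 of 402 were not detected in pup 1. Below 1 TPM the shares were 51.2% and 26.5%. Of 96 ERCC spike-ins, 26 were detected in both libraries, 15 in pup 1 only, 3 in pup 3 only and 52 in neither.

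**Figure D1:**
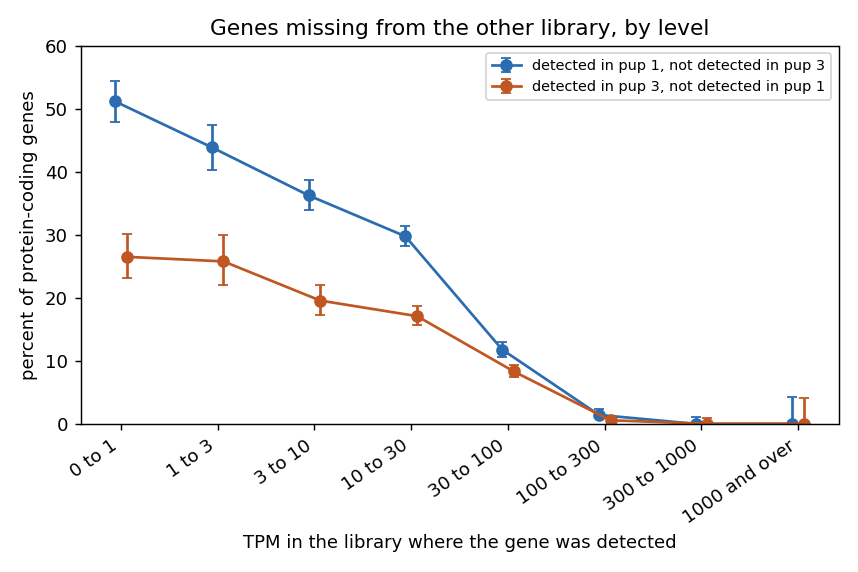
Percent of protein-coding genes detected in 1 library (expected count of at least 5) and not in the other, against the deposited TPM in the library where they were detected; points are shares, bars are 95% Wilson intervals, and colours give the direction. The share missing in pup 3 was 51.2% below 1 TPM and 1.42% at 100 to 300 TPM.

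Across the 13847 genes, log2(TPM + 1) of the deposited TPM in the pups correlated with a Pearson coefficient of 0.578 and a Spearman coefficient of 0.546. Over the 8931 genes detected in both libraries the coefficients were 0.722 and 0.714. These are correlations across genes, which are not independent replicates. Differences by level were taken over protein-coding genes detected in both libraries, grouped by the geometric mean of deposited TPM, so genes missing from 1 library are left out. The 82 genes at 1000 TPM and over differed between pups by a median of 1.39-fold and the 350 at 300 to 1000 TPM by 1.39-fold. The 2539 at 30 to 100 TPM differed by 1.74-fold and the 1195 at 3 to 10 TPM by 5.20-fold. The 44 ERCC spike-ins detected in at least 1 library correlated with a Pearson coefficient of 0.783, and the 26 detected in both with 0.971.

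**Figure D2:**
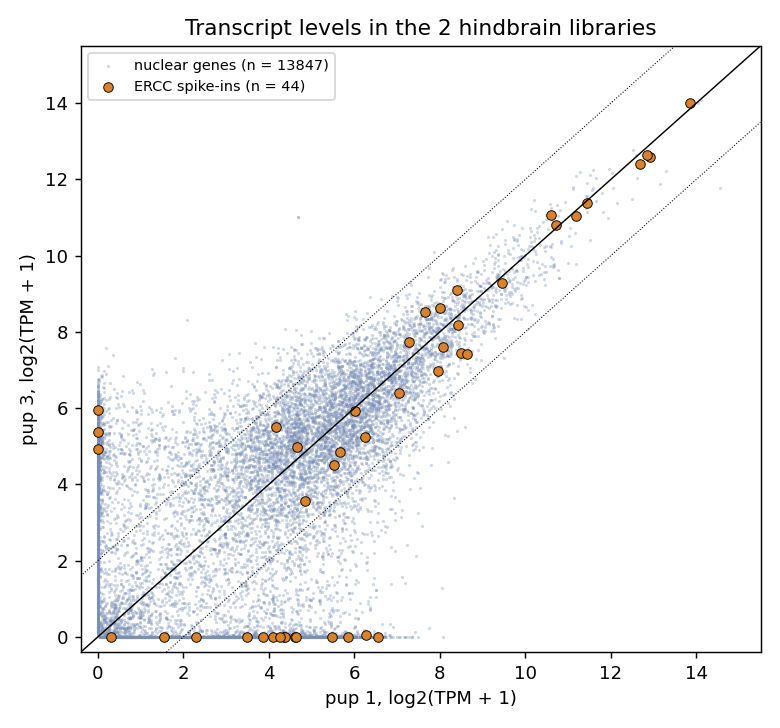
Level of each nuclear gene detected in at least 1 library (small points, n = 13847) and each ERCC spike-in detected in at least 1 library (orange, n = 44) in pup 1 and pup 3, both axes log2(TPM + 1), with TPM rescaled for genes and as deposited for spike-ins; the solid line is equality and the dotted lines a 4-fold difference. Along the axes lie genes missing from 1 library, among them most of the 4916 detected in 1 library only.

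Hoxb5 (ENSMUSG00000038700.4, chromosome 11, 96303336 to 96306121) was the highest of the Hox genes of paralog groups 1 to 5, which pattern the hindbrain and upper cord, at 109 ± 21.9 TPM. Hoxa5 was at 17.3 ± 2.95 TPM, Hoxc4 at 13.2 ± 1.89 TPM and Hoxa2 at 12.99 ± 3.75 TPM. In this list 6 of 15 genes were detected in both libraries (random lists of protein-coding genes of the same size, 2 to 9 in the central 95%). Of the Hox genes of paralog groups 6 to 13, which mark the trunk, 0 of 24 were (random lists 5 to 14). Hoxb7, Hoxb6 and Hoxa6 were detected in pup 3 only, at 25.6, 24.7 and 20.6 TPM, at least 211-fold, at least 225-fold and at least 110.4-fold higher than in pup 1, and Hoxb8 had 7 and 0 counts in pup 1 and pup 3. Among hindbrain and cerebellar factors, 13 of 29 were detected in both libraries (random lists 6 to 16), led by the Hox cofactors Meis1 (211 ± 23.7 TPM) and Meis2 (147 ± 22.96 TPM). Tfap2b, Pou4f1, Zic4, Pax3 and Zic1 were at 39.3 ± 36.4, 36.99 ± 17.4, 25.3 ± 2.16, 22.9 ± 2.71 and 20.5 ± 8.96 TPM. Egr2, Gbx2 and Atoh1 had 0 counts in both. Forebrain factors were detected in both libraries for 2 of 22 genes (random lists 4 to 13), Neurod6 at 33.99 ± 21.7 TPM and Otx1 at 8.79 ± 1.24 TPM. Eomes was at 8.83 TPM in pup 3 with 0 counts in pup 1. Emx1, Dlx1 and Six3 had 0 counts in both. The forebrain count was 4 when 1 count was enough for detection. Hox genes lie in clusters with overlapping and antisense transcripts, and whether strand was used in counting is not given in the sources used here.

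Genes listed for the developing cerebellum were detected in both pups above the range of random lists. Random lists were drawn from all protein-coding genes, of which 37.8% were detected in both libraries. An excess over them does not by itself mark the cerebellum. In the granule cell lineage list 15 of 20 members were detected in both pups (random lists 3 to 12), with Nfix at 139 ± 128 TPM, Reln, the secreted layering signal, at 105 ± 21.3 TPM, Nfib at 92.9 ± 10.8 TPM and Nfia at 63.8 ± 59.03 TPM. Neurod1 was at 44.4 ± 1.94 TPM and the synapse organiser Cbln1 at 38.7 ± 1.32 TPM. Gabra6, a receptor subunit of mature granule cells, had 0 counts in both, and so had the list members Atoh1 and Gli1. Mycn, also in this list, was detected in pup 1 only. Among Purkinje cell genes 11 of 16 were detected in both (random lists 2 to 10), led by Pcp4 at 723 ± 66.3 TPM, with Ebf1 at 114 ± 0.662 TPM, Car8 at 86.5 ± 7.89 TPM and Pcp2 at 78.1 ± 19.3 TPM. Calb1 was at 109 TPM in pup 1 and 29.7 TPM in pup 3.

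Neuronal genes were captured throughout. All 22 pan-neuronal genes were detected in both libraries (random lists 4 to 13), with medians of 404 TPM in pup 1 and 452 TPM in pup 3. The highest were Stmn1, the neuronal beta tubulin Tubb3 (2975 ± 1316 TPM), Stmn3 (1988 ± 624 TPM) and Stmn2 (1928 ± 528 TPM), and Gap43, a growth cone protein, was at 1712 ± 22.8 TPM. Of the synaptic vesicle and postsynaptic genes 23 of 24 were detected in both (random lists 5 to 14), with Rab3a at 659.7 ± 24.7 TPM, Syt11 at 330.2 ± 208 TPM, Vamp2 at 318 ± 14.1 TPM and Cplx1 at 246 ± 86.9 TPM. Syn2 was the exception, at 17.3 TPM in pup 1 and 0.0558 TPM in pup 3.

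Glutamatergic, GABAergic and glycinergic genes stood side by side. Glutamatergic genes were detected in both pups for 12 of 15 members (random lists 2 to 9). The AMPA receptor subunit Gria2 was at 206 ± 50.4 TPM, the vesicular transporter Slc17a6 at 88.9 ± 26.5 TPM and Grm5 at 42.3 ± 17.8 TPM. The transporter Slc17a7 had 0 counts in both. GABA and glycine genes were detected in both for 15 of 18 members (random lists 3 to 11), with the GABA-synthesising enzyme Gad1 at 113 ± 9.63 TPM and the glycine transporter Slc6a9 at 69.5 ± 42.9 TPM. The neuronal glycine transporter Slc6a5 was at 20.8 ± 2.16 TPM. Genes of monoamine and acetylcholine nuclei were detected in both for 6 of 18 members (random lists 3 to 11). Ache was at 54.6 ± 51.96 TPM, Maoa at 49.9 ± 15.9 TPM, the serotonin-synthesising enzyme Tph2 at 28.8 ± 21.4 TPM and Gata3 at 28.2 ± 18.95 TPM. The 6 members seen in pup 1 only included Slc18a2 (29.1 TPM), Th (22.99 TPM) and the serotonin transporter Slc6a4 (8.49 TPM), each with 0 counts in pup 3. The list's medians were 15.8 TPM in pup 1 and 0.0558 TPM in pup 3, and the median log2 ratio of pup 3 over pup 1 across members detected in at least 1 library was -1.30, inside the range of matched random lists (-1.71 to 1.06).

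Astrocyte and radial glial genes were detected in both pups for 22 of 24 members (random lists 5 to 14). Apoe (3380.2 ± 219.8 TPM), the radial glial lipid-binding protein Fabp7 (2901 ± 156 TPM), Dbi (2336 ± 553 TPM) and Aldoc (827 ± 83.6 TPM) were the highest. Aldh1l1 and Hopx were the 2 members missing from pup 3, where Aldh1l1 had 1 count against 6228 in pup 1 and Hopx 0 against 235. Oligodendrocyte precursor genes were detected in both for 6 of 11 members (random lists 1 to 7), with Pdgfra at 28.5 ± 1.26 TPM, Vcan at 21.2 ± 12.7 TPM, Tnr at 17.4 ± 9.59 TPM and Olig1 at 16.7 ± 3.76 TPM. Gpr17, a gene of cells committing to myelination, was at 21.04 TPM in pup 1 with 0 counts in pup 3. Myelin genes were detected in both for 6 of 14 members (random lists 2 to 9), with Mbp at 251 ± 72.3 TPM and Cnp at 102 ± 48.7 TPM. Cldn11 was at 18.8 ± 8.52 TPM, and Mobp at 20.6 TPM in pup 1 with 0 counts in pup 3. The myelin count was 3 when detection was set at 1 TPM.

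Vascular, immune, blood and barrier transcripts were present beside the neural ones. Microglia and macrophage genes were detected in both pups for 6 of 17 members (random lists 3 to 10), with Laptm5 at 89.2 ± 43.3 TPM, the complement gene C1qb at 80.1 ± 36.00 TPM and Ctss at 47.03 ± 30.3 TPM. Csf1r, Trem2, Tyrobp, Fcer1g and Aif1 were seen in pup 1 only, and Cd68, Fcrls, P2ry12 and Cx3cr1 in pup 3 only. Endothelial and pericyte genes were detected in both for 9 of 17 members (random lists 3 to 10), with Vtn at 191 ± 69.4 TPM, the tight junction gene Cldn5 at 121 ± 49.9 TPM, Esam at 73.7 TPM in pup 1 and 0.145 TPM in pup 3 and Egfl7 at 27.04 ± 25.7 TPM. Erythroid genes were detected in both for 7 of 14 members (random lists 2 to 9), with adult globins Hba-a2 at 763 TPM in pup 1 and 1911 TPM in pup 3, Hbb-bs at 231 TPM in pup 1 and 1101 TPM in pup 3 and Hba-a1 at 255 TPM in pup 1 and 657 TPM in pup 3. The globin pairs share reads, and the embryonic globins Hbb-y, Hbb-bh1 and Hba-x had 0 counts. Meningeal and fibroblast genes were detected in both for 11 of 16 members (random lists 2 to 10), led by Ptgds at 3329 ± 1409 TPM, Dcn at 126 ± 58.2 TPM, Slc6a13 at 95.9 ± 15.1 TPM and Igf2 at 91.4 ± 50.4 TPM. Choroid plexus genes were detected in both for 6 of 14 members (random lists 2 to 9). The thyroxine carrier Ttr was at 3204 ± 249 TPM, Enpp2 at 155 ± 17.4 TPM and Folr1 at 63.9 ± 13.2 TPM, whereas Otx2 was at 0.113 TPM in pup 1 and 85.1 TPM in pup 3. Of the ependymal and cilia genes 2 of 11 were detected in both (random lists 1 to 7), Mlf1 at 63.3 ± 52.2 TPM and Foxj1 at 7.81 ± 3.37 TPM. Rarres2 and Cfap43 were seen in pup 1 only, at 25.99 and 23.7 TPM.

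Among cartilage, muscle and skin genes 1 of 14 were detected in both pups (random lists 2 to 9), the muscle actin Acta1 at 14.2 TPM in pup 1 and 44.7 TPM in pup 3. Tnnt3, Matn1 and Krt10 were seen in pup 1 only, at 11.3, 8.85 and 4.30 TPM. Among liver, pancreas and pituitary genes 2 of 14 were (random lists 2 to 9), namely Ttr, which the choroid plexus list also holds, and Apoa1 at 4.48 TPM in pup 1 and 36.1 TPM in pup 3. Alb, Afp, Ins1, Gh and Prl had 0 counts in both.

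**Figure D3:**
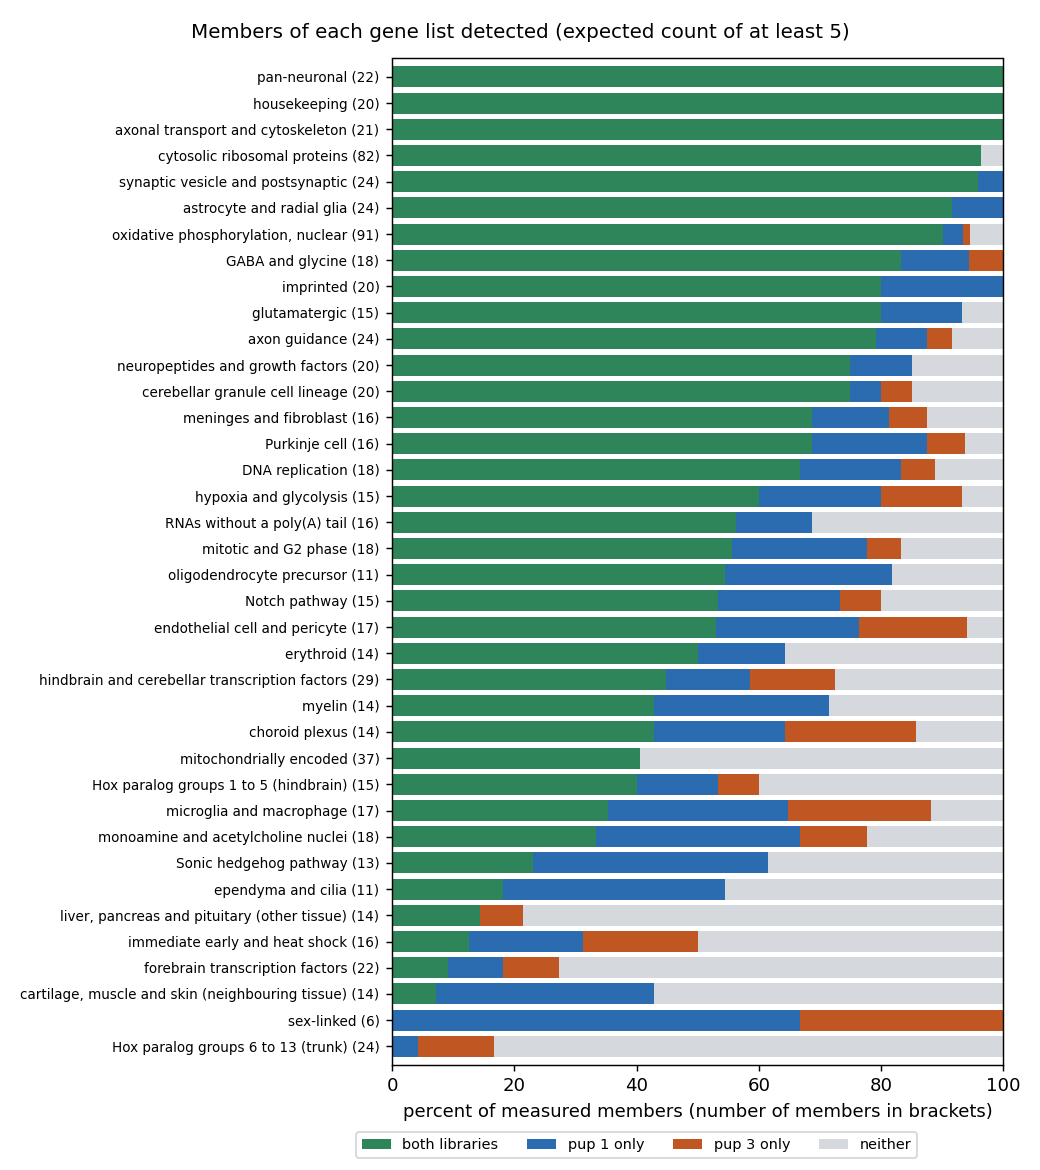
Percent of the measured members of each gene list that were detected (expected count of at least 5) in both libraries, in pup 1 only, in pup 3 only or in neither; the number of measured members is in brackets. Pan-neuronal, housekeeping and cytoskeletal genes were detected in both pups throughout, and 0 of 24 trunk Hox genes were.

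Proliferation genes were present in both animals. Mitotic and G2 phase genes were detected in both for 10 of 18 members (random lists 3 to 11), with cyclin Ccnb1 at 103 ± 2.87 TPM, Cdk1 at 82.3 ± 36.1 TPM, Plk1 at 51.9 ± 19.8 TPM and Cenpf at 40.02 ± 22.1 TPM, and Mki67 at 8.57 ± 0.3996 TPM. DNA replication genes were detected in both for 12 of 18 members (random lists 3 to 11), with Pcna at 23.4 TPM in pup 1 and 154 TPM in pup 3, Tipin at 87.2 ± 40.2 TPM, Rrm2 at 123 TPM in pup 1 and 24.1 TPM in pup 3 and Mcm6 at 73.3 ± 20.8 TPM. Sonic hedgehog pathway genes were detected in both for 3 of 13 members (random lists 2 to 8), with the co-receptor Boc at 38.98 ± 5.10 TPM, the receptor Ptch1 at 15.4 ± 3.59 TPM and Sufu at 13.3 ± 4.25 TPM. Mycn, not detected in pup 3, was at 24.9 TPM in pup 1 and 0.0223 TPM in pup 3. The ligand Shh and the transcription factor Gli1 had 0 counts in both. This count was 5 when 1 count was enough for detection. Notch pathway genes were detected in both for 8 of 15 members (random lists 2 to 9), with Hes5 at 56.4 TPM in pup 1 and 7.78 TPM in pup 3, Dll3 at 20.2 ± 3.98 TPM, Notch1 at 17.3 ± 3.54 TPM and Mfng at 0.655 TPM in pup 1 and 29.4 TPM in pup 3. Axon guidance genes were detected in both for 19 of 24 members (random lists 5 to 14), with Dpysl2, a transducer of guidance signals, at 1266 ± 683 TPM, Robo2 at 54.6 ± 24.5 TPM, Epha7 at 40.8 ± 19.5 TPM and Unc5c at 36.7 ± 15.3 TPM.

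Hypoxia and glycolysis genes were detected in both pups for 9 of 15 members (random lists 2 to 9), with Eno1 at 1369.9 ± 240.4 TPM, Pkm at 1036 ± 161 TPM, Ldha at 799 ± 209 TPM and Pfkp at 298 ± 139 TPM. Vegfa was at 2.28 TPM in pup 1 with 0 counts in pup 3. Immediate early and heat shock genes were detected in both for 2 of 16 members (random lists 2 to 10), the chaperone Dnajb1 at 119 ± 34.6 TPM and Jund at 0.803 ± 0.0332 TPM. Fos had 0 and 2093 counts in pup 1 and pup 3, Btg2 2382 and 0 and Egr1 0 and 115. With detection at 1 TPM, 1 member of this list was detected in both.

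Ribosomal protein genes were higher in pup 1. Of 82 cytosolic ribosomal protein genes 79 were detected in both (random lists 23 to 40), and 72 of these 79 had more TPM in pup 1 and 7 more in pup 3. Their median log2 ratio of pup 3 over pup 1 was -0.69, outside the central 95% of 10000 lists matched on mean expression (-0.11 to 0.28), and lay between -0.79 and -0.61 under every scaling tried. Rpl41 was at 4557 TPM in pup 1 and 2675 TPM in pup 3, Rps19 at 2924 TPM in pup 1 and 1365 TPM in pup 3, Rps14 at 2069 TPM in pup 1 and 1459 TPM in pup 3 and Rpl32 at 2055 TPM in pup 1 and 902 TPM in pup 3. Nuclear genes of oxidative phosphorylation were detected in both for 82 of 91 members (random lists 25 to 44), with Atp5b at 1987 ± 1141 TPM, Cox6b1 at 1773 ± 278 TPM, Ndufa4 at 1755 ± 793 TPM and Cox6a1 at 1520.3 ± 341 TPM, and a median log2 ratio of 0.23 (-0.13 to 0.28 in matched lists). Of 37 mitochondrially encoded genes 15 were detected in both and 22, all transfer RNA genes under the 200 nt size limit, in neither. Relative to the nuclear total, mt-Atp8 was at 13967 ± 4277 TPM, mt-Atp6 at 12462 ± 168 TPM, mt-Cytb at 6944 ± 119 TPM and mt-Nd1 at 6749 ± 463 TPM.

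Among nuclear non-coding transcripts the highest included copies of mitochondrial sequence on chromosome 1. Gm28437, Gm28661, Gm10925, Gm29216 and Gm28438 were at 16619.8 ± 133, 7406 ± 3686, 6404 ± 3734, 6294 ± 192 and 2658 ± 117 TPM, and their reads cannot be told from those of the mitochondrial genes they resemble. Malat1, a nuclear-retained long RNA (ENSMUSG00000092341.2, chromosome 19, 5795690 to 5802672), was at 6443 ± 766 TPM, and Gm37376, which lies inside it, at 2869 ± 83.04 TPM. Gm22133, an annotated microRNA precursor inside Ftl1, was at 3703 ± 1084 TPM, and the pseudogene Gm10123 at 3261 ± 306 TPM. The Gm22133 level came from 608 counts in pup 1 and 816 in pup 3, scaled to a short locus (chromosome 7, 45458089 to 45458197). Gm26917, with 32672 counts in pup 1, was at 488 TPM there. The rank of Gm22133 thus rests on its length, which is below the size limit of the RNA used. Whether its reads came from Ftl1 transcripts was not tested. Gm42418 (ENSMUSG00000098178.1, chromosome 17, 39846958 to 39848788) was at 23907 TPM in pup 1 and 3481 TPM in pup 3. RNAs without a poly(A) tail were detected in both pups for 9 of 16 members (random lists 3 to 10). Rn7s1 and Rn7s2, near-identical genes of the signal recognition particle RNA, were at 24.9 TPM in pup 1 and 2052 TPM in pup 3 and at 24.9 TPM in pup 1 and 2051 TPM in pup 3, the histone gene Hist1h2ap at 383 ± 104 TPM and Rn7sk at 210.5 ± 64.4 TPM. The median log2 ratio of this list was -0.38 (-0.70 to 0.91 in matched lists), although Rn7s1 and Rn7s2 were higher in pup 3.

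Between the pups, the largest differences were transcripts captured in 1 library and missing or nearly missing from the other. Of 12300 genes with at least 50 counts in a library, 5009 (40.7%) differed at least 4-fold on the log2(TPM + 1) scale, 2956 higher in pup 1 and 2053 higher in pup 3. Among the 5009, 1798 were detected in both libraries, and of these 807 (44.9%) were higher in pup 1 and 991 in pup 3, so the excess toward pup 1 lay in genes missing from pup 3. Examples detected in both are Arpc3, a subunit of the actin-nucleating Arp complex, at 264 TPM in pup 1 and 1.44 TPM in pup 3, and Pabpn1, a nuclear poly(A)-binding protein, at 3.23 TPM in pup 1 and 319 TPM in pup 3. Higher in pup 1 were Agt (at least 1764-fold), Dnajc2 (at least 1893-fold), Armcx1 (at least 1732-fold), Slc25a14 (at least 1348-fold), Rit1 (at least 807-fold), Fam173a (at least 765-fold), Emc9 (at least 657-fold) and Cmc2 (at least 449-fold), all with 0 counts in pup 3. Mtx1, a mitochondrial import gene, had 2305 and 1 counts, a share 1948-fold (95% counting interval 349 to 76992) higher in pup 1, and Ubl7 had 4451 and 2 counts, a share 1881-fold (95% counting interval 520.5 to 15539) higher. Higher in pup 3 with 0 counts in pup 1 were Tmed3 (at least 1092-fold), Psmg2 (at least 886-fold) and Psmc3ip (at least 746-fold). Ccdc12, Fbxw9, Pgap2, Mrps23, Gmnn, Mrpl40 and Clpx had 191, 167, 136, 126, 115, 116 and 108 TPM in pup 3 and between 1 and 10 counts in pup 1. The count of 4-fold differences was 2873 with a pseudocount of 5 and 7707 for a 2-fold difference.

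The labels give no sex, and sex-linked transcripts split the animals. The Y-linked genes Eif2s3y, Ddx3y and Uty were at 114, 77.3 and 33.8 TPM in pup 1 with 0 counts in pup 3, at least 999-fold, at least 1688-fold and at least 675-fold higher in pup 1. Kdm5d, also Y-linked, had 164 and 3 counts in pup 1 and pup 3. Xist, the RNA of the inactive X chromosome (ENSMUSG00000086503.3, chromosome X, 103460366 to 103483254), had 2 and 17094 counts. Tsix, its antisense partner, had 0 and 472, and reads of the pair cannot be told apart without strand. None of the 6 members was detected in both.

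Of 39 gene lists, 37 had at least 5 members detected and were compared between the pups as groups. The sex-linked list (-3.17 against -2.07 to 1.74 in matched lists) and the ribosomal proteins lay outside the central 95%, and 1.85 lists would by chance. Members of the sex-linked list went opposite ways, with 4 Y-linked genes higher in pup 1 and 2, Xist and Tsix, higher in pup 3. The sign of its median thus depends on how many of each were listed. Housekeeping genes lay close to the edge at -0.34 (-0.34 to 0.51, percentile 2.54), with 12 of 20 members higher in pup 1. Neuronal and glial lists lay inside it, with 0.35 for pan-neuronal genes (-0.31 to 0.52), -0.28 for astrocytes and radial glia (-0.50 to 0.57) and -0.80 for myelin (-1.21 to 0.89).

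Transcript usage was shared for abundant genes. Of 5681 genes with several annotated transcripts and at least 50 counts in each library, 3619 (63.7%) had the same most abundant transcript in both pups, where drawing at random among the annotated transcripts would give 22.7%. The share was 62.8% of 473 genes at a mean below 10 TPM, 50.9% of 1518 at 10 to 30 TPM, 61.3% of 2297 at 30 to 100 TPM, 77.5% of 987 at 100 to 300 TPM and 92.9% of 406 at 300 TPM and over. In the list of genes known for alternative transcripts, detected in both pups for 15 of 15 members (random lists 2 to 9), 13 had several transcripts and 8 of these shared the top one. Cdc42 (1105 ± 352 TPM), Pkm (1036 ± 161 TPM), Mapt (715 ± 374 TPM) and Snap25 (592 ± 15.4 TPM) were the highest. The leading transcript of Snap25 took 95.5% of the gene in pup 1 and 99.9% in pup 3, and that of Pkm 74.9% and 51.9%. Mbp, Mapt, Map2, Nfasc and Tpm1 differed. For Mbp, transcript ENSMUST00000142850.3 took 46.0% in pup 1 and 0% in pup 3, where ENSMUST00000133193.3 led with 27.1%. For the microtubule-binding protein Mapt, ENSMUST00000106992.5 took 44.2% in pup 1 and 30.7% in pup 3, and ENSMUST00000106993.5 took 38.4% and 44.3%.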

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

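No test in this part was chosen only after the result was seen. Among the entries that carry a number for a name, which no comparison used, pup 1 had 10.99 expected counts and pup 3 had 0. This was picked out because it is a signal outside the main measurement, above the 3 counts that a count of 0 allows. The 10.99 counts fell on 2 entries, 22050 with 4.99 and 48727 with 6. What these entries stand for is not given in the sources used here, and no explanation was tested.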

How the results depend on the processing

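The alternatives on scaling over protein-coding genes, on scaling to the spike-ins and on genes detected in both libraries were chosen after seeing the data. The counts of genes detected in both libraries and in only 1 library stayed within 1.5 times under all 4 alternatives each, and no list changed the sign of a difference called outside its random range. The Pearson coefficient of 0.578 on deposited TPM was 0.419 with a pseudocount of 0.1, 0.696 with 5, 0.641 with no filter, 0.722 over genes detected in both libraries, 0.607 with FPKM and 0.546 with CPM. The 5009 genes differing 4-fold were 2873 with a pseudocount of 5, 7707 at 2-fold and 1798 among genes detected in both libraries, and stayed within 1.5 times under the other 9 alternatives. The share of genes with the same top transcript was 65.6% with at least 200 counts. The number of members detected in both libraries changed by over 1.5 times in 6 of 117 alternatives: with 1 count enough, forebrain factors had 4, Sonic hedgehog 5, cartilage, muscle and skin 2 and sex-linked 2, and at 1 TPM myelin had 3 and immediate early 1. List differences moved by more than the SD of the differences of random lists in 12 of 146 alternatives: with a pseudocount of 0.1 to -1.81 for myelin, 0.92 for microglia, -1.19 for endothelial cells, -5.55 for ependyma, -1.53 for Sonic hedgehog, -4.99 for cartilage, muscle and skin and -5.99 for sex-linked genes, with a pseudocount of 5 to -0.95 for ependyma, -0.71 for cartilage, muscle and skin and -1.65 for sex-linked genes, and with DESeq2 size factors to -0.79 for ribosomal proteins and 0.13 for oxidative phosphorylation. This SD was 0.0915 for ribosomal proteins and 0.724 for hindbrain factors, whose difference of -0.88 was -0.33 with a pseudocount of 5. With a pseudocount of 0.1, forebrain factors went from 0.34 to 0.84 and the Notch pathway from -0.70 to -1.24, also within it. Median list levels in TPM moved by more than the SD of the medians of the pups, which is wide where the pups differ, under deposited TPM to Hox groups 1 to 5 2.33, cerebellar granule cell lineage 22.5, pan-neuronal 415, synaptic vesicle and postsynaptic 51.3, glutamatergic 19.6, GABA and glycine 28.8, astrocyte and radial glia 107, mitotic and G2 phase 21.1, DNA replication 21.8, Notch pathway 2.43, axon guidance 12.2, axonal transport and cytoskeleton 911, housekeeping 1018, immediate early and heat shock 0.163, RNAs without a poly(A) tail 39.8 and oxidative phosphorylation, nuclear 397. Under FPKM, another unit, they were Hox groups 1 to 5 1.54, hindbrain and cerebellar transcription factors 1.88, cerebellar granule cell lineage 15.03, Purkinje cell 17.96, pan-neuronal 279, synaptic vesicle and postsynaptic 34.3, glutamatergic 13.03, GABA and glycine 19.4, astrocyte and radial glia 72.03, microglia and macrophage 14.7, erythroid 14.2, meninges and fibroblast 21.3, choroid plexus 9.14, mitotic and G2 phase 14.1, DNA replication 14.6, Notch pathway 1.61, axon guidance 8.27, axonal transport and cytoskeleton 616, housekeeping 682, immediate early and heat shock 0.105, RNAs without a poly(A) tail 26.6, imprinted 15.8, neuropeptides and growth factors 33.9, isoform genes 177, cytosolic ribosomal proteins 356 and oxidative phosphorylation, nuclear 267. Over the single libraries they ranged as follows: Hox groups 1 to 5 0 to 0.102, hindbrain and cerebellar transcription factors 0.793 to 1.76, cerebellar granule cell lineage 19.1 to 22.6, Purkinje cell 22.2 to 28.6, pan-neuronal 404 to 452, synaptic vesicle and postsynaptic 50.9 to 53.3, glutamatergic 18.9 to 19.1, GABA and glycine 27.5 to 27.8, monoamine and acetylcholine nuclei 0.0558 to 15.8, astrocyte and radial glia 106 to 121, oligodendrocyte precursor 3.53 to 10.6, meninges and fibroblast 34.01 to 42.4, choroid plexus 1.24 to 6.50, mitotic and G2 phase 16.97 to 19.7, DNA replication 22.7 to 23.6, Notch pathway 2.03 to 2.43, axon guidance 11.03 to 11.7, axonal transport and cytoskeleton 879.8 to 898, housekeeping 997 to 1131, immediate early and heat shock 0 to 0, sex-linked 0.0112 to 17.6, RNAs without a poly(A) tail 35.9 to 36.5, imprinted 30.9 to 43.3, neuropeptides and growth factors 28.96 to 54.5, isoform genes 302 to 377, oxidative phosphorylation, nuclear 384 to 431. Within that SD the single libraries gave myelin 0 to 6.33, microglia and macrophage 21.3 to 25.7, endothelial cell and pericyte 2.27 to 15.9, erythroid 17.7 to 29.98, ependyma and cilia 0 to 3.70, Sonic hedgehog pathway 0 to 0.260, hypoxia and glycolysis 27.6 to 57.2, cartilage, muscle and skin 0 to 0.0113, cytosolic ribosomal proteins 437 to 689. Of 555 alternatives for named genes, 25 moved the mean level, all under deposited TPM. The shifts under deposited TPM follow from its total, of which nuclear genes took 88.6% in pup 1 and 89.6% in pup 3. For the other shifts the cause was not tested. No paired analysis was possible because there is 1 group.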

Other observations

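Imprinted and secreted-peptide genes, not described so far, were well captured. Of the imprinted genes 16 of 20 were detected in both libraries (random lists 3 to 12), with Nnat at 2569.9 ± 208 TPM (n = 2), Snrpn at 1329 ± 139.6 TPM, Ndn at 1213 ± 399.8 TPM and the non-coding Meg3 at 1007 ± 579.6 TPM. Gnas was at 337 ± 128 TPM, Rian at 228 ± 34.3 TPM and Mest at 63.6 TPM in pup 1 and 376 TPM in pup 3. The 4 members missing from pup 3 were Grb10, Magel2, Zrsr1 and Plagl1, with 35.8, 11.2, 8.66 and 6.26 TPM in pup 1. Of the neuropeptides and growth factors 15 of 20 were detected in both (random lists 3 to 12). The growth factor Ptn was at 489 ± 88.7 TPM, somatostatin (Sst) at 455 ± 70.4 TPM, proenkephalin (Penk) at 349.8 ± 41.2 TPM and the substance P precursor Tac1 at 239 ± 81.8 TPM. Galanin (Gal) was at 127 TPM in pup 1 with 0 counts in pup 3, and Npy had 729 and 1 counts. Vip had 0 counts in both.

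The tests of the cell type makeup, of Gm42418 against random capture and of both explanations for the sex-linked transcripts were chosen after the results were seen. The tests with spike-ins and with thinning were written down before. The test with Gm26917 is also recorded as written before, although that gene is among those named after their values were seen.

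Genes detected in 1 library only numbered 4916. Sequencing depth as the cause of their uneven split is argued against: thinning pup 1 to the depth of pup 3 ended 4.87% of the excess of genes seen in pup 1 only, from 1724 to 1640. Random capture of few molecules stays open. Of 44 spike-ins detected at least in 1 library, 18 were in 1 library only, above the central 95% (8 to 17) of mouse genes matched on level and length, so RNAs that carry no biology of the animals were lost at least as often, though not at the matched rate that was predicted. A different cell type makeup of the 2 hindbrains also stays open, since 2 of 37 lists lay outside the central 95% against 1.85 by chance, and these were the sex-linked and the ribosomal protein lists. Neither is a list of a cell type. Some cell type lists had wide matched ranges, such as -2.81 to 1.87 for oligodendrocyte precursors, so this count could miss a difference in makeup.

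Gm42418 was 6.87-fold higher in pup 1. Random capture of few molecules stays open. The absolute log2 ratio of 2.78 lay at percentile 98.4 of 126 other genes with a mean of at least 1000 TPM, where the median was 0.50 and 2 genes, Rn7s1 and Rn7s2, lay beyond it, but the gene was picked for its ratio, so this rank decides nothing. The locus overlaps over 1245 of its 1831 nt with Rn18s-rs5, an 18S ribosomal RNA-related sequence on chromosome 17, from 39846354 to 39848202 in the RefSeq annotation of GRCm38. Ribosomal RNA carried into the library may account for it, but the neighbouring Gm26917, which is also known to collect ribosomal RNA reads, had a ratio of 1.03, neither the 2-fold excess predicted nor the absence of one. AY036118, the other locus that the prediction named, was not listed and could not be checked. No biological explanation was tested.

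For the sex-linked transcripts, random capture of few molecules is argued against, since the chance that Ddx3y, Eif2s3y and Uty were all missed in pup 3, from the shares missed among autosomal genes of like level in pup 1 (8.14%, 3.95% and 21.6%, taken as independent), was 0.000694. A mixed sample stays open at small shares. The Xist count in pup 1 was 0.0117% of that in pup 3, and the 3 Y-linked genes together had 0 counts in pup 3 against 11439 in pup 1, where 3 counts would be 0.0262%. These percentages cover counting error only. At 1 percent of their level in pup 1, the 3 genes would all be missed in pup 3 with a chance of 0.118, and 25.0% of autosomal genes at 1 percent of the Xist level in pup 3 were missed in pup 1. Kdm5d, not among the 3 Y-linked genes of these tests, had 3 counts in pup 3, 1.83% of its 164 in pup 1. The prediction against a mixed sample asked for Kdm5d under 1 percent, which was not met. That both pups were of the same sex is argued against by these genes. The 3 Y-linked genes had 11439 counts in pup 1 and 0 in pup 3. Xist went the other way, with 0.0117% of its pup 3 count in pup 1. The labels do not give the sex, and it was not checked by other means.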
